A study of Mus musculus with 6 samples.

How the data were processed

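Single-cell RNA sequencing by Drop-seq, a droplet method that tags each messenger RNA with a cell barcode and a unique molecular identifier (UMI), was available for 6 libraries of 4T1 mouse breast tumours. Per the labels, 3 libraries came from tumours given FVIO-MHT and 3 from tumours given PBS, all taken 24 hours later. The deposited matrices hold whole-number UMI counts per gene and barcode, which the authors made with STAR 2.7.2b on the mm10 genome build, per the submitters' processing notes. The counting tool, the gene annotation, the use of strand and the choice of barcodes are not given in the sources used here. Each matrix lists 5000 barcodes and 27998 genes. A total of 65 rows that repeat a gene symbol with identical counts were dropped, which left 27933 genes, and 27624 of their identifiers matched the GENCODE annotation used for gene positions (GRCm38, the build also called mm10, counted from 1).

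The total count was 706300, 1391802 and 2207534 UMIs in FVIO-MHT replicates 1, 2 and 3, and 1381844, 2100443 and 678337 UMIs in PBS replicates 1, 2 and 3. Barcodes were kept as cells with at least 200 detected genes and at most 20% mitochondrial UMIs. The gene minimum kept 6730 barcodes. The mitochondrial limit removed 0 of them, so the alternative without that limit tests nothing. Scrublet, run in scanpy 1.11.5 with an expected rate of 5% per library, called 30 doublets, or 0.446% of the barcodes. A caller that marks under 0.5% was set beforehand to count as not working, so doublets are treated as not removed, although those 30 were left out. The 6700 cells that remained numbered 331, 1044 and 2319 in FVIO-MHT replicates 1 to 3 and 1078, 1453 and 475 in PBS replicates 1 to 3, with median depths between 400 and 833 UMIs per cell. With 0 cells seen, 3 counts of the total set the share that is allowed, up to 0.906% in FVIO-MHT replicate 1 and up to 0.129% in FVIO-MHT replicate 3. Intervals and floors cover counting error only.

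Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 17 clusters. Cell class markers, gene lists, tests, filters and the rule for named genes were fixed before the data were examined. Naming a cluster needed at least 3 markers of a class, each detected in at least 5% of its cells. Each had to lie 2-fold or more over the median of the clusters. All markers of the class had to average 2-fold or more on the log scale. The 10 leading genes of the cluster could not point to another class. Tumour epithelial was assigned last, against the clusters already named, where no other class was met. None of the 10 leading genes of any tumour epithelial-like cluster is among its markers. The details of this naming rule were settled after the clusters' leading genes and the cell counts per library had been seen, and before any comparison between groups. In all, 4 versions were tried, and the last is used. The version before it left cluster 15, which is led by Apoe, C1qa and C1qc and holds 394 of the 438 macrophage/monocyte-like cells of FVIO-MHT replicate 3, without a name, and it is reported as the stricter naming. Cluster 15 also carries 4 tumour epithelial markers. The stricter naming leaves out clusters of other classes with at least 3 of them. This left 13 named clusters and 4 unnamed ones. The unnamed clusters are led by genes of skin epithelium, of mammary luminal epithelium or of osteoclasts, or carry markers of erythroid and tumour epithelial cells together. The sets for skin, mammary luminal epithelium and osteoclasts were chosen after the leading genes had been seen. At these settings no cluster was named NK, dendritic, mast/basophil, erythroid, platelet, skeletal muscle or adipocyte. The T and NK-like class is cluster 9 alone, which was named T. At Leiden resolution 2 an erythroid class held 454 of 2319 cells of FVIO-MHT replicate 3. At a minimum of 100 genes it held 763 of 4677.

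UMI counts were summed per library over all kept cells and over each of 5 classes, taking a library with at least 20 cells of the class. FVIO-MHT was compared with PBS by edgeR 4.0.16 (quasi-likelihood test, TMM normalisation, filterByExpr, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. The standard error of a log2 fold change is its size divided by the square root of the F statistic. With no pairing by animal in the labels, the design holds the group only. The macrophage/monocyte-like comparison had 3 against 3 libraries, tumour epithelial-like 2 against 3, fibroblast-like 2 against 2, neutrophil-like 2 against 1, and T and NK-like 1 against 3. Where a group has 1 library, that library is assumed to vary like those of the other group. Counts were also simulated with up to 200 genes changed, fewer in T and NK-like cells. Each gene was drawn independently, and simulated libraries did not differ in cell clusters as real ones can. The shares found can therefore overstate what the test finds here. At 4-fold, changed genes were 180 of 8131 tested in whole tumours and 176 of 709 in T and NK-like cells. Shares are therefore not comparable between comparisons. Of genes changed 4-fold, the test found 13.9% in the whole tumour comparison, 80.5% in macrophage/monocyte-like and 71.8% in tumour epithelial-like cells. It found 33.5% in T and NK-like, 6.01% in fibroblast-like and 0% in neutrophil-like cells. For genes changed 2-fold, it found 0.541% in tumour epithelial-like cells, 0.575% in T and NK-like cells and 0% in the other 4 comparisons.

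A total of 22 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01 where at least 5 members were tested, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, in 1 direction, and it does not compare them with other genes. Shares of cells were compared by a two-sided exact permutation test over libraries, adjusted over 9 classes. Its two-sided p is the smaller one-sided p times 2. With 3 libraries against 3 its smallest possible p is 0.1. Shares per library have exact Clopper-Pearson 95% intervals. The level of a tested gene is given in CPM (UMIs of the gene scaled to the total of the summed class after TMM normalisation), as mean ± SD over libraries. In barcodes under the gene minimum, CPM use the plain total without TMM.

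Named genes are the 10 largest changes per direction past the threshold, list members past it, and otherwise the 5 lowest p values per direction, together with genes named in advance for each class. Genes named in the text outside this rule are said to be chosen after their values were seen. Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, replicate number as a block, each library left out, gene minimums of 100 and 400, doublets kept, thinning to the smallest library, all barcodes, Leiden resolutions of 0.5 and 2, and other set tests. Added after seeing the data were the stricter naming, removal of barcodes found in more than 1 library, removal of the unnamed cluster with markers of 2 classes, and a comparison without PBS replicates 2 and 3. The last was added after the differential expression had been seen.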

Results

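The data describe tumours grown from 4T1 cells, a mouse mammary carcinoma line, in Balb/c mice. FVIO-MHT, mild magnetic hyperthermia, pairs iron oxide nanorings, injected at 0.1 mg per cm3 of tumour, with 10 min in a field that alternates at 365 kHz and warms them. Tumours were dissociated 24 hours later, and 3 libraries per group were sequenced. The comparison asks how the cells of a treated tumour, and its macrophages in particular, differ from those given PBS. The labels carry 1 protocol text for all 6 samples, so whether PBS tumours also met the field is not given in the sources used here. They do not say that replicates came from separate mice, so p-values measure the spread between these libraries. Total depth ran from 678337 to 2207534 UMIs per library, and the kept cells numbered between 331 and 2319.

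Neutrophil-like cells made up 79.8% of FVIO-MHT replicate 1 (95% Clopper-Pearson interval 75.0 to 84.0%) and 37.6% of FVIO-MHT replicate 2 (34.7 to 40.7%), but 0.216% of FVIO-MHT replicate 3 (0.0700 to 0.502%). In PBS tumours they held 6.03%, 0.619% and 1.68%. Tumour epithelial-like cells, which carry keratins and Epcam, were 12.4% ± 10.7 (SD, n = 3) of cells with FVIO-MHT and 49.1% ± 20.3 (SD, n = 3) with PBS. Every FVIO-MHT library lay below every PBS library, an order lost at Leiden resolution 2 and at both other gene minimums. At Leiden resolution 2 the share was 48.6% in FVIO-MHT replicate 3 and 36.8% in PBS replicate 3. At a minimum of 100 genes it was 47.6% in FVIO-MHT replicate 3 and 18.2% in PBS replicate 1, and at 400 genes 72.7% in FVIO-MHT replicate 3 and 51.1% in PBS replicate 3. FVIO-MHT replicate 1 had 0 tumour epithelial-like cells among 331, which at 3 counts of the total allows a share of up to 0.906% and has a Clopper-Pearson upper bound of 1.11%. Macrophage/monocyte-like cells, the class with complement C1q genes and Csf1r, were 19.8% ± 1.21 (SD, n = 3) against 14.2% ± 5.01 (SD, n = 3). T and NK-like cells were 1.66% ± 2.47 against 11.0% ± 9.60 (SD, n = 3 each), and B/plasma-like cells came almost wholly from PBS replicate 1, with 176 cells. In the two-sided exact permutation test the p was 0.1 for tumour epithelial-like, 0.2 for T and NK-like, 0.3 for macrophage/monocyte-like, 0.4 for neutrophil-like and 0.7 for B/plasma-like shares. The smallest p that 3 against 3 libraries allow is 0.1, and each adjusted p was 0.9.

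Stromal classes were small in both groups. Fibroblast-like cells held 3.52% ± 2.29 with FVIO-MHT and 2.99% ± 3.12 with PBS (SD, n = 3 each), endothelial-like cells 2.20% ± 2.42 and 1.66% ± 0.569, and pericyte/smooth muscle-like cells 0.972% ± 0.897 and 0.457% ± 0.343. Their exact permutation p was 0.9, 0.9 and 0.5. Cells in unnamed clusters made up 20.2% ± 26.9 and 12.5% ± 10.7 (SD, n = 3 each; exact permutation p = 0.8). Of these, a cluster with both haemoglobin and keratin transcripts held 50.4% of FVIO-MHT replicate 3 and between 0 and 5.56% of the other 5 libraries. Cells led by mammary luminal genes held 2.13%, 2.34% and 7.79% of PBS replicates 1, 2 and 3 and at most 0.0958% of any FVIO-MHT library. Cells led by skin keratins ranged from 0 to 3.54% with FVIO-MHT and from 0.0928 to 15.4% with PBS, and osteoclast-led cells reached at most 0.670% of a library. At a minimum of 100 genes, where the clusters were also drawn and named anew, the difference of group means went from −36.7 to −16.3 percentage points for tumour epithelial-like cells and from 5.63 to −1.01 points for macrophage/monocyte-like cells. With the stricter naming the latter was 0.573 points. Unnamed clusters held 50.8% of FVIO-MHT replicate 3 as reported, 1.92% at a minimum of 100 genes and 0.517% at Leiden resolution 2 with the gene minimum unchanged, so the naming and the gene minimum are not separated in the tumour epithelial-like difference.

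**Figure D1:**
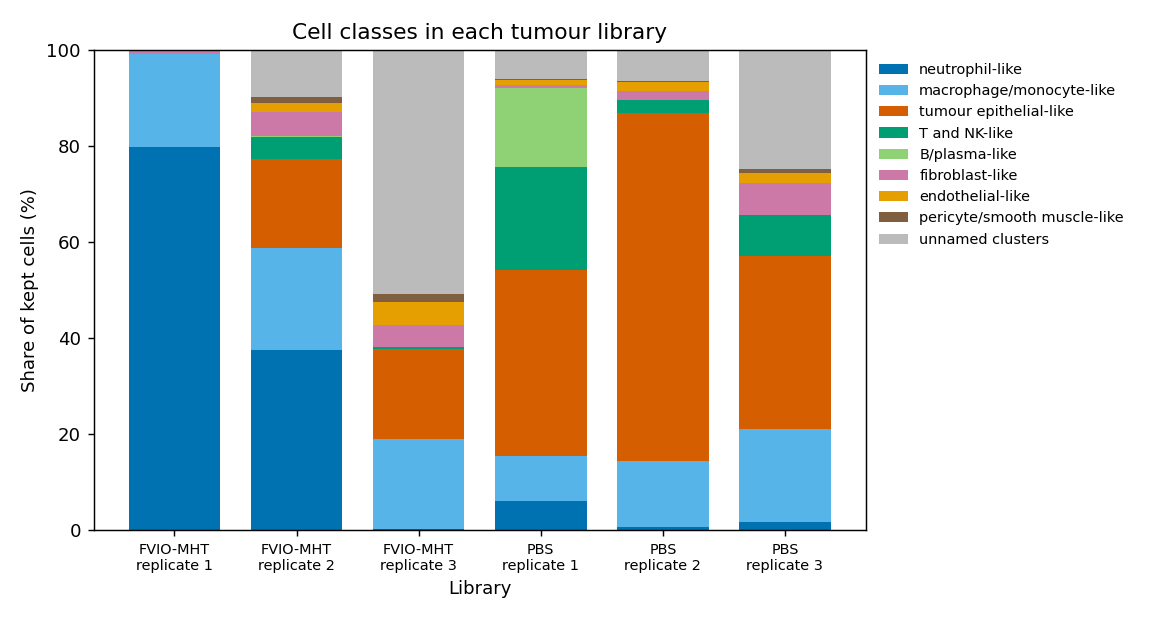
Stacked bars give the share of kept cells (%) in each named class and in unnamed clusters for each of the 6 libraries. Neutrophil-like cells reach 79.8% and 37.6% in FVIO-MHT replicates 1 and 2 and 0.216% in replicate 3, and unnamed clusters fill 50.8% of FVIO-MHT replicate 3.

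Over whole tumours, no gene passed the threshold. The genes below are those with the lowest p values and those named in advance. Rsad2, an interferon-induced antiviral gene (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), averaged 560 ± 121 CPM with FVIO-MHT and 83.6 ± 37.0 CPM with PBS (SD, n = 3 each), 6.70-fold apart. Isg15, named in advance, encodes an interferon-induced ubiquitin-like protein and averaged 1019 ± 488 and 245 ± 39.5 CPM. C5ar1, the receptor for complement C5a on myeloid cells, had a log2 fold change of 3.90 ± 0.97 (SE), and Ctsk, a collagen-degrading cathepsin, one of 2.82 ± 0.69. Ctsk is a leading gene of the osteoclast-led cluster. That cluster held 0, 7 and 8 cells in FVIO-MHT replicates 1 to 3 and 2, 0 and 0 in PBS replicates 1 to 3. In the other direction, the mammary genes Wfdc18 (−6.67 ± 0.99), Prlr, the prolactin receptor (−5.93 ± 1.13), and Ptn, a growth factor (−4.30 ± 1.04), led, and all 3 are leading genes of the mammary luminal cluster that came almost wholly from PBS libraries. H19, an imprinted noncoding RNA, differed by −3.24 ± 0.78. Lrrc25 and Cd93, both expressed on myeloid cells, and H2-DMb2, an MHC class II loading chaperone, were 5.42 ± 1.33, 2.33 ± 0.49 and −2.09 ± 0.50. Among genes named in advance, Hmox1, which degrades haem, differed by 3.29 ± 1.07, Fth1 and Ftl1, the ferritin chains, by 1.94 ± 1.07 and 1.46 ± 0.89, and Cd274, which encodes PD-L1, by 2.78 ± 1.30. These 4 values rest on FVIO-MHT replicate 1: without it they were 1.02, 0.36, −0.05 and 1.22. Also without it, C5ar1 was 2.86 and Lrrc25 3.85. Ctsk was 1.95 without FVIO-MHT replicate 2, Wfdc18 −5.49 without FVIO-MHT replicate 3, and Prlr −4.57 and Ptn −3.04 without PBS replicate 3. The heat shock genes Hspa1a, Hspa1b, Hsp90aa1 and Hspb1 differed by −3.87 ± 1.07, −3.94 ± 1.10, −1.16 ± 0.64 and −2.28 ± 1.03, the last by −1.21 without PBS replicate 3. Hspa1a held 62.6, 27.5 and 37.3 CPM in FVIO-MHT replicates 1 to 3, 45.1 CPM in PBS replicate 1 and 548 and 1172 CPM in PBS replicates 2 and 3. Hspa1b held 35.8, 223 and 125 CPM, 190 CPM, and 3146 and 2730 CPM in the same order. For these genes the edgeR adjusted p lay between 0.853 and 0.886.

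Camera called 13 of the fixed lists in whole tumours with its preset correlation. All 13 calls were lost with an estimated correlation, where the adjusted p ran from 0.502 to 0.696, and with fry, and over all alternatives the adjusted p of these lists ran from 5.45e-15 to 0.902. The neutrophil suppressive and activation list had a median log2 fold change of 3.62, with 14 of 14 members higher and 10 past the threshold when adjusted over the list alone, and it moved with the neutrophil-like share. Myeloid chemokines (1.42), extracellular matrix genes (1.03), M1-like macrophage genes (1.02), iron handling genes (0.93), checkpoint genes (1.23), macrophage lipid and lysosome genes (0.84) and hypoxia genes (0.56) were also called higher by camera with the preset correlation alone. Heat shock genes (−1.19, 5 of 18 lower when adjusted over the list alone), MHC class II (−1.22) and class I genes (−0.82), T and NK cytotoxicity genes (−1.11) and ribosomal proteins (−0.50) were called lower. Not called were the lists of type I interferon (0.35), M2-like macrophage (0.55), p53 (0.77), immediate early (0.33), mesenchymal (0.16), unfolded protein response (−0.11), nuclear oxidative phosphorylation (−0.03) and mitochondrially encoded genes (−0.63). The cell cycle list had a positive median (0.38) and a camera direction that was lower, without a call. The count of genes past the threshold was 0 of 8582 tested by edgeR, with 454 at an unadjusted p under 0.05, against 180 by DESeq2 (163 higher, 17 lower). Without FVIO-MHT replicate 1 the hypoxia median was −0.29, past the threshold in the other direction, and the calls of checkpoint (0.19), M1-like (0.37) and iron handling genes (0.18) ended. Without FVIO-MHT replicate 2 the M1-like (0.76) and checkpoint calls (0.46) ended, and without FVIO-MHT replicate 3 those of MHC class I (−0.51), MHC class II (−0.87) and T and NK cytotoxicity genes (−0.35). Calls also ended without PBS replicate 1 (M1-like 1.33, checkpoint 1.00, hypoxia 0.47), PBS replicate 2 (M1-like 1.06, checkpoint 0.85) and PBS replicate 3 (T and NK cytotoxicity −0.69), and without both PBS replicates 2 and 3 (M1-like 1.60, checkpoint 1.71). With replicate number as a block the checkpoint call ended too (0.79). Other medians moved by more than 1.5 times while their call stayed. Without FVIO-MHT replicate 1 these were neutrophil (1.503), MHC class I (−0.48), MHC class II (−0.79), T and NK cytotoxicity (−0.65), lipid and lysosome (0.51) and ribosomal genes (−0.16). Without FVIO-MHT replicate 2 they were iron handling (0.56), MHC class I (−2.02), MHC class II (−2.55) and T and NK cytotoxicity genes (−3.67), and without FVIO-MHT replicate 3 heat shock (−1.82), hypoxia (0.92) and ribosomal genes (−1.03). Iron handling genes were 0.54 without PBS replicate 1 and 0.51 without PBS replicate 2, and without PBS replicate 3 M1-like genes were 1.87, chemokines 2.19 and lipid and lysosome genes 1.36. Without both PBS replicates 2 and 3, heat shock genes were −0.53, MHC class I −0.51, chemokines 3.73, extracellular matrix 1.67 and lipid and lysosome genes 1.59.

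In macrophage/monocyte-like cells, Hspa1a and Hspa1b, which encode the inducible heat shock protein HSP70, lay lower in every FVIO-MHT library than in every PBS library, without passing the threshold. This separation did not extend to Hsp90aa1, at 3537 CPM in FVIO-MHT replicate 3 and 1730 CPM in PBS replicate 1. Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238) averaged 45.1 ± 46.0 CPM with FVIO-MHT and 2355 ± 2362 CPM with PBS (SD, n = 3 each), a log2 fold change of −5.31 ± 1.03 (SE) from 20 and 677 UMIs. Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) differed by −5.09 ± 1.04, and both had an edgeR adjusted p of 0.495. These neighbouring genes are nearly identical, so reads can be split between them. PBS replicates 2 and 3 held 4899 and 1935 CPM of Hspa1b and PBS replicate 1 held 232 CPM. The class drew on different clusters, which a comparison of the summed class reads as a difference: cluster 15 gave 90.0% of it in FVIO-MHT replicate 3 and at most 9.78% elsewhere, where cluster 1 gave most. Cluster 15 also carries 4 tumour epithelial markers. Values of this class in FVIO-MHT replicate 3 therefore rest mostly on a cluster with markers of both classes. The interferon gene Rsad2 was 2.15 ± 0.55 and Isg15 1.44 ± 0.67, while S100a9, a neutrophil granule gene, was 4.30 ± 1.19. Without FVIO-MHT replicate 1 S100a9 was 2.80, without FVIO-MHT replicate 3 Rsad2 was 1.47, and without PBS replicate 2 Hspa1b was −4.17. Barcodes under the gene minimum hold free RNA, cells of low depth or both, and at a minimum of 100 genes 1457 of 1572 barcodes of FVIO-MHT replicate 1 were neutrophil-like. Neutrophil marker RNA in barcodes under the gene minimum was 77728, 35537 and 2600 CPM in FVIO-MHT replicates 1 to 3 and 17451, 3887 and 9582 CPM in PBS replicates 1 to 3.

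Polarisation genes of macrophages showed no common direction. Among markers of the inflammatory, M1-like state, Nos2 differed by 1.38 ± 1.28, Il1b by 0.13 ± 0.54, Tnf by −0.01 ± 0.59, Cxcl9 by −0.80 ± 1.05, Cxcl10 by −0.84 ± 0.52 and Cd86 by −0.29 ± 0.56 (log2 ± SE). Among M2-like markers, Mrc1, the mannose receptor, differed by −0.98 ± 0.44, with every FVIO-MHT library below every PBS library, and Arg1, arginase, by 0.12 ± 1.09. Single libraries set several of these values. Without FVIO-MHT replicate 1 Arg1 was −3.18, Nos2 −0.28, Il1b −0.63 and Tnf −0.82. That library held 4518 CPM of Arg1, and the other FVIO-MHT libraries 95.7 and 202 CPM. Without FVIO-MHT replicate 2 Cxcl9 was −5.41 and Cd86 −1.31, and without PBS replicate 2 Cxcl10 was −0.23. H2-Aa, an antigen-presenting MHC class II chain, was −1.34 ± 0.73, Trem2 0.11 ± 0.57, Sirpa, the receptor for CD47, 0.39 ± 0.44, and Cd274 −0.21 ± 0.80. Hmox1 was 0.83 ± 0.53, Fth1 0.24 ± 0.50, Ftl1 0.01 ± 0.53 and Hsp90aa1 −1.11 ± 0.63. Ier2, Ndufb9 and Btg1 (1.48 ± 0.50, 1.38 ± 0.47 and 2.05 ± 0.70) and Gadd45b, Prpf4b and Rbbp6 (−1.70 ± 0.42, −1.62 ± 0.41 and −1.66 ± 0.43) completed the lowest p values. Among these, H2-Aa was −2.69 and Cd274 −1.29 without FVIO-MHT replicate 2, Btg1 was 0.75 without FVIO-MHT replicate 1, Ndufb9 was 0.82 without FVIO-MHT replicate 3, and Hsp90aa1 was −0.42 without PBS replicate 2. The edgeR adjusted p of these genes was between 0.861 and 0.997. Hspb1, Cd163, Chil3 and Il10 had too few UMIs to test, with 3, 6, 21 and 8 in FVIO-MHT libraries and 16, 4, 2 and 5 in PBS libraries.

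Of 21 lists tested in macrophage/monocyte-like cells, 5 were called by camera with the preset correlation. With an estimated correlation the adjusted p of all 5 was 0.697, which ended the calls, and over all alternatives theirs ran from 2.32e-15 to 0.915. Heat shock (median −1.03, 0 of 12 members positive, 3 lower when adjusted over the list alone), MHC class II (−1.11, 0 of 9 positive) and MHC class I (−0.30, 3 of 11 positive) were called lower. Myeloid chemokines (1.25, 10 of 12 positive) and immediate early genes (0.59, 12 of 16 positive), which also respond to tissue dissociation, were called higher, again with the preset correlation alone. The M1-like list had a median of −0.01 (camera adjusted p = 0.501) and the M2-like list one of 0.11 with a lower camera direction (camera adjusted p = 0.803). Of 2071 genes, edgeR put 0 past the threshold and 87 at an unadjusted p under 0.05, and DESeq2 put 2 past it, Hspa1a and Hspa1b, as did edgeR without PBS replicate 1. The camera calls of chemokines and immediate early genes ended without FVIO-MHT replicate 1 (medians 0.36 and 0.23) and without PBS replicate 1 (1.07 and 0.44), that of chemokines also without FVIO-MHT replicate 3 (0.46), and that of MHC class I without FVIO-MHT replicate 1 (−0.01) or 3 (0.07); without PBS replicates 2 and 3 the heat shock median was 0.10 and that of MHC class I −0.05, and both calls ended. Medians of calls that stayed moved by more than 1.5 times for heat shock without FVIO-MHT replicate 3 (−2.09) or PBS replicate 2 (−0.52), MHC class I without FVIO-MHT replicate 2 (−1.28), and chemokines (1.94) and immediate early genes (1.31) without PBS replicates 2 and 3.

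**Figure D2:**
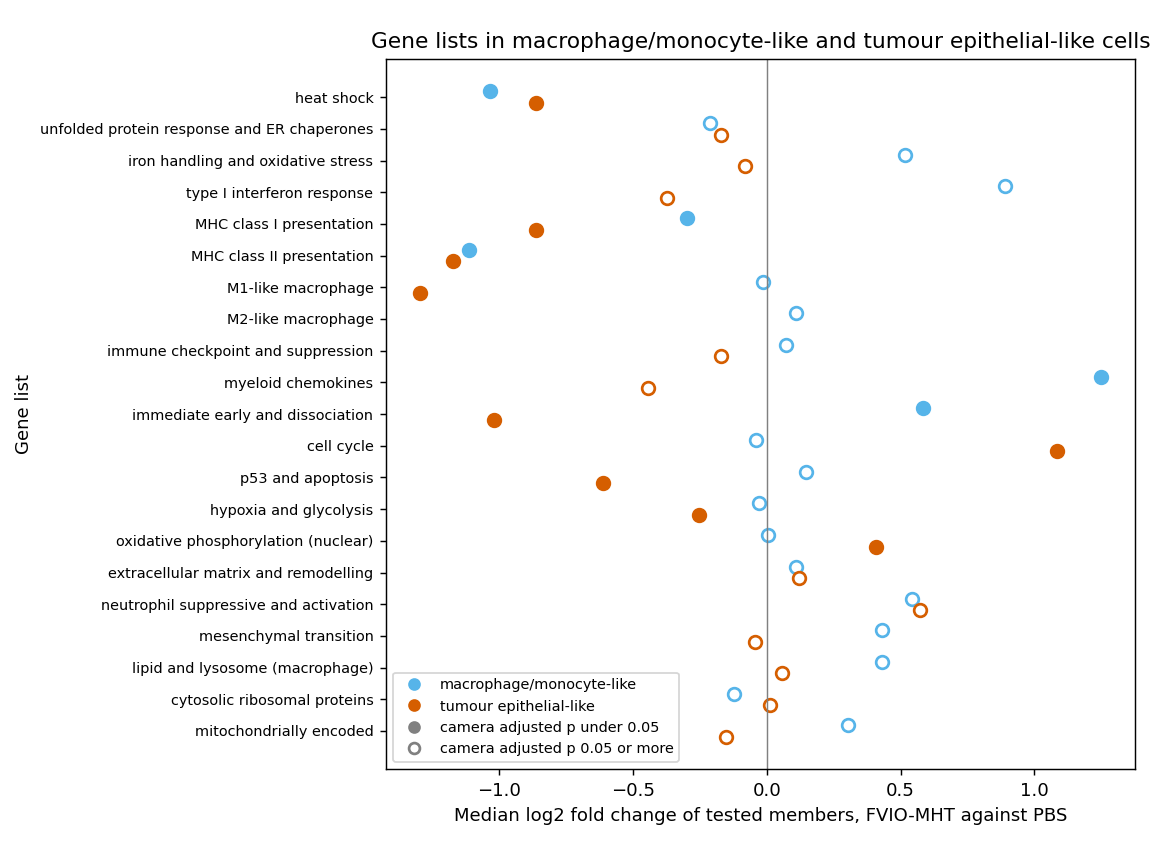
Points give the median log2 fold change, FVIO-MHT against PBS, of the tested members of each gene list (vertical axis) in macrophage/monocyte-like cells (blue) and tumour epithelial-like cells (orange). Filled points have a camera adjusted p under 0.05 with the preset correlation, and heat shock genes sit at −1.03 and −0.86.

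In tumour epithelial-like cells no gene passed the threshold. The lowest p values included cell cycle genes on the higher side and stress-response genes on the lower side. Ccna2, a cyclin of S and G2 phases (ENSMUSG00000027715, chromosome 3, 36564865 to 36572150), averaged 117 ± 31.2 CPM (SD, n = 2) against 32.7 ± 3.88 CPM (SD, n = 3), a log2 fold change of 1.82 ± 0.34 (SE). Ncapd2, a condensin subunit, and the linker histone Hist1h1e were 1.64 ± 0.36 and 1.97 ± 0.43, and Mki67 was 0.08 ± 0.35. Pitx1 and Ifrd2 were 2.53 ± 0.52 and 2.57 ± 0.59. On the lower side, Atf3, a stress-induced transcription factor (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039), averaged 300 ± 121 against 1506 ± 366 CPM, and the early-response factors Egr2 and Maff were −2.81 ± 0.50 and −2.17 ± 0.42. H19 was −3.82 ± 0.61 and the noncoding Gm26917 −1.63 ± 0.31. Hspa1a had 0 UMIs with FVIO-MHT and 113 with PBS, at least 19.2-fold lower against a floor of 3 counts over the group. Hspa1b was −2.89 ± 0.94, from 436 and 168 CPM in FVIO-MHT replicates 2 and 3, 226 CPM in PBS replicate 1 and 3289 and 3157 CPM in PBS replicates 2 and 3. Hsp90aa1 was −0.93 ± 0.36, Cdkn1a −0.70 ± 0.31 and Vegfa −1.20 ± 0.51. Cd47 and Calr, a signal against and a signal for engulfment, were −0.17 ± 0.35 and −0.17 ± 0.34, and Gpx4, which guards against lipid peroxidation, was 0.16 ± 0.53. Hmox1, Fth1, Ftl1, Isg15 and Cd274 were 0.26 ± 0.47, −0.18 ± 0.44, −0.59 ± 0.36, 0.18 ± 0.43 and −1.22 ± 0.76. With FVIO-MHT replicate 2 left out, Cd274 (−3.59), Vegfa (−2.33) and Isg15 (−0.82) were lower. With FVIO-MHT replicate 3 left out Cd274 was −0.12, Vegfa −0.52 and Gpx4 −0.84. Each of these fits left a single FVIO-MHT library. Hist1h1e, Pitx1 and Maff were 1.01, 1.85 and −1.73 without FVIO-MHT replicate 3, and Ifrd2 was 1.97 without PBS replicate 2. Signs also changed for Hmox1 (−0.22 without FVIO-MHT replicate 2) and Fth1 (0.32 without PBS replicate 1). Hspb1 had too few UMIs to test. All of these had edgeR adjusted p values between 0.367 and 0.968.

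Among lists in these cells, camera called 9 with the preset correlation. With an estimated correlation their adjusted p ran from 0.548 to 0.748, which ended the calls, and over all alternatives from 1.12e-16 to 0.918. Cell cycle genes had a median of 1.08, with 22 of 24 positive and 12 past the threshold when adjusted over the list alone. Their summed level was 3556 and 6257 CPM in FVIO-MHT replicates 2 and 3 and 2582, 3071 and 3702 CPM in PBS replicates 1, 2 and 3, so FVIO-MHT replicate 2 lay below PBS replicate 3. Nuclear oxidative phosphorylation genes had a median of 0.41, with 21 of 25 positive. Called lower, with the preset correlation alone, were immediate early genes (−1.02, 9 of 16 lower when adjusted over the list alone), heat shock (−0.86, 6 of 17), M1-like genes (−1.29, 4 of 7), MHC class II (−1.17, 1 of 10), MHC class I (−0.86, 0 of 12), p53 (−0.61, 2 of 11) and hypoxia genes (−0.25, 0 of 19). The M1-like and MHC class II genes are expressed by macrophages too. The tumour epithelial-like class was spread unevenly. Cluster 4, led by the cell cycle genes Birc5, Ube2c and Ccna2, gave 91.9% of it in FVIO-MHT replicate 3. Cluster 5 gave 60.3% in FVIO-MHT replicate 2 and 71.5% in PBS replicate 1. Clusters 6 and 11, led by H19 and by Hspa1b among others, gave 48.4 and 44.7% in PBS replicate 2. In PBS replicate 3 they gave 47.4 and 36.8%. Cluster 11 gave 2.06 and 0.463% in FVIO-MHT replicates 2 and 3 and 3.59% in PBS replicate 1. Of 7471 genes tested, edgeR put 0 past the threshold (692 at an unadjusted p under 0.05) and DESeq2 put 26 (1 higher, 25 lower). Without FVIO-MHT replicate 2 edgeR put 248 past it, of which 79 were higher, with Ccna2, Pitx1, Hist1h1e, Ncapd2, H19, Atf3, Egr2 and Maff among them, and without PBS replicate 1 it put 10, with H19, Hspa1a and Hspa1b among them. Without FVIO-MHT replicate 3, 6 calls ended, with medians of 0.03 for MHC class I, −0.50 for MHC class II, −1.20 for M1-like, 0.24 for hypoxia, −0.48 for p53 and 0.03 for oxidative phosphorylation genes; the p53 call also ended without PBS replicate 2 (−0.34) or 3 (−0.68), and without both of these the p53 (−0.24) and oxidative phosphorylation calls (0.38) ended. Calls stayed but medians moved by more than 1.5 times without FVIO-MHT replicate 2 (MHC class I −2.41, MHC class II −5.33, M1-like −2.29, hypoxia −1.31), without FVIO-MHT replicate 3 (cell cycle 0.55) and without PBS replicate 2 (M1-like −0.74). The same was seen without both PBS replicates 2 and 3 (heat shock −0.28, MHC class I −0.41, MHC class II −0.76, hypoxia −0.39).

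**Figure D3:**
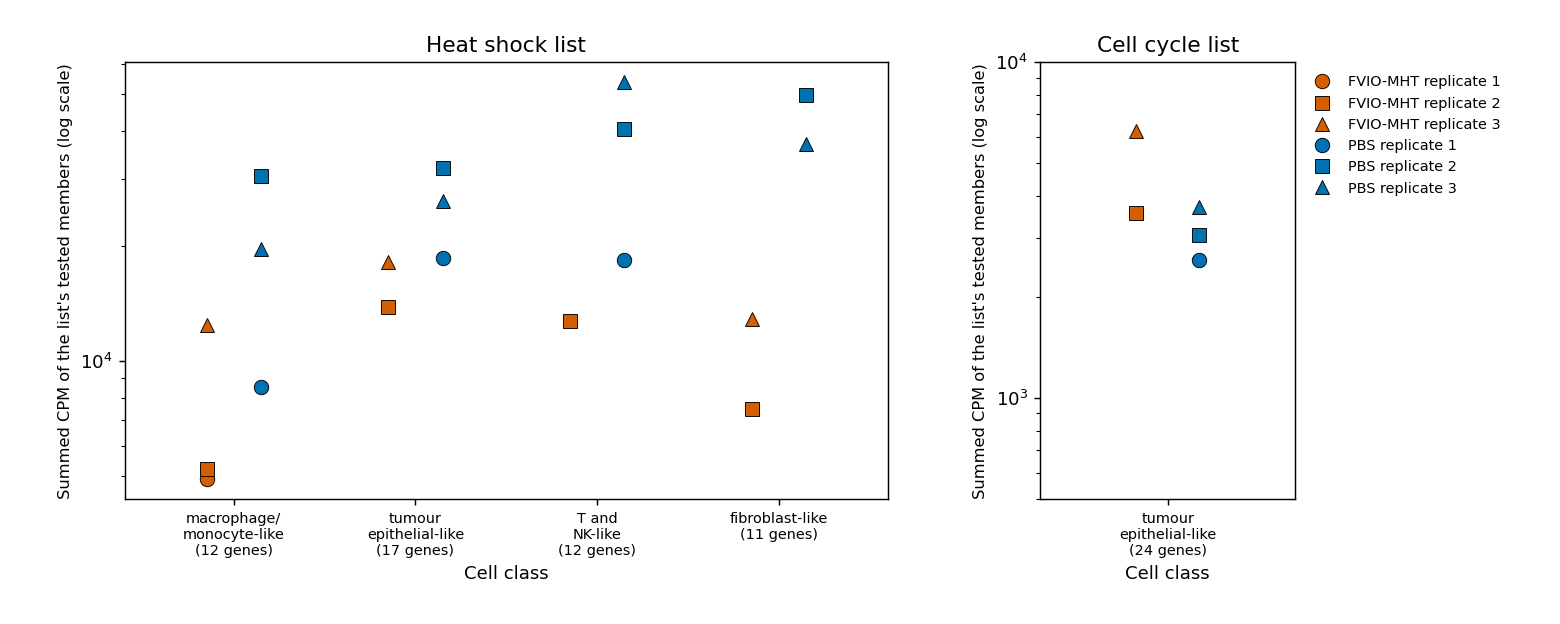
Points give the summed CPM (log scale) of the tested members of the heat shock list in 4 cell classes and of the cell cycle list in tumour epithelial-like cells, for each library with at least 20 cells of the class. PBS replicates 2 and 3 are the highest for heat shock in each class, at 30391 and 19601 CPM in macrophage/monocyte-like cells, and FVIO-MHT replicate 3 is the highest for the cell cycle, at 6257 CPM.

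Neutrophil-like cells reached 20 cells in FVIO-MHT replicates 1 and 2 and PBS replicate 1. The immediate early factor Egr1 averaged 1585 ± 139 CPM (SD, n = 2) against 153 CPM in the lone PBS library, a log2 fold change of 3.37 ± 1.00 (SE). Irf2, Bax, Gnas and Usp32 had 0 UMIs in that library, which puts them at least 1.85, 1.48, 1.48 and 1.45-fold higher with FVIO-MHT against a floor of 3 counts. Camp, a granule peptide of immature neutrophils, was −2.84 ± 0.78, Satb1 −5.00 ± 0.91 from 5 and 16 UMIs, Cntrl −3.26 ± 0.99, Rapgef6 −2.52 ± 0.80 and Gm26917 −5.61 ± 0.85. Hmox1, Fth1, Ftl1, Hsp90aa1, Isg15 and Cd274 were 0.73 ± 1.16, 0.21 ± 1.20, 0.85 ± 1.02, 0.54 ± 0.91, 0.83 ± 1.00 and 0.61 ± 0.80. Hspa1a, Hspa1b and Hspb1 had too few UMIs to test. Immediate early (median 1.51) and M1-like genes (1.15, or 0.63 with genes at 0 set to the floor) were called higher by camera, and MHC class II (−1.57) and ribosomal proteins (−0.93) lower, around a median of 0.16 over all genes. All 4 calls were lost with an estimated correlation and with fry. A fit of 2 against 1 libraries leaves these tests little to estimate spread from, and the estimated correlation of MHC class II genes was 1. The loss of the calls therefore decides nothing. Of 18 heat shock genes 6 could be tested, with a median of 0.48, 4 of 6 positive and no call (camera adjusted p = 0.849). In barcodes under the gene minimum, B/plasma marker RNA was 0 and 4.07 CPM in FVIO-MHT replicates 1 and 2 and 511 CPM in PBS replicate 1, and dendritic marker RNA 9.52, 102 and 939 CPM. Satb1 is also a leading gene of the T and B clusters. Different clusters held the class, with cluster 0 giving 98.5% of it in FVIO-MHT replicate 1, and cluster 2 giving 89.3% in FVIO-MHT replicate 2 and 86.2% in PBS replicate 1. Of 2595 genes, edgeR put 0 past the threshold (51 at an unadjusted p under 0.05; adjusted p of the named genes 0.993) and DESeq2 put 1, Gm26917.

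T and NK-like cells could be compared between FVIO-MHT replicate 2 and the 3 PBS libraries. The class held cluster 9 alone, which was named T, and no cluster was named NK. Saa3, an acute-phase protein gene, was 3.23 ± 0.69 (log2 fold change ± SE), from 36 UMIs against 25, and Lmna, Vim, Btg1 and S100a6 were 3.02 ± 0.85, 2.03 ± 0.57, 1.71 ± 0.61 and 1.53 ± 0.58. Without PBS replicate 1, Saa3 was 4.41 and Btg1 2.34. Hspa1a had 0 UMIs against 64, at least 3.98-fold lower at a floor of 3 counts, while Hsp90aa1, the chaperonin subunit Hspe1, Fam46a and Smc4 were −2.01 ± 0.67, −3.00 ± 1.07, −3.53 ± 1.19 and −2.24 ± 0.81. Hspa1b was −2.19 ± 1.15, Fth1 1.13 ± 0.43, and Ftl1 −2.01 ± 0.86. Gzmb, a cytotoxic granule protease, had 1211 CPM against 1267 ± 1202 CPM (SD, n = 3), and its log2 fold change was 1.03 without PBS replicate 2. Prf1, Ifng, Pdcd1, Lag3, Isg15, Cd274, Hmox1 and Hspb1 were too sparse to test. Camera called heat shock genes lower (median −2.72, or −2.24 with genes at 0 set to the floor) and mesenchymal genes higher (0.96), both with an adjusted p of 0.619 with an estimated correlation and between 4.33e-14 and 0.677 over their alternatives. Fibroblast marker RNA in barcodes under the gene minimum was 4066 CPM in FVIO-MHT replicate 2 and 87.8, 379 and 2824 CPM in PBS replicates 1, 2 and 3. T and NK cytotoxicity genes had a median of 0.71 (camera adjusted p = 0.171). The edgeR adjusted p of the named genes lay between 0.230 and 0.997. Of 714 genes, edgeR put 0 past the threshold (34 at an unadjusted p under 0.05) and DESeq2 put 0, but edgeR put 16 past it without PBS replicate 1 and 1 without PBS replicate 3, and the mesenchymal call ended without PBS replicate 1 (1.13).

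Fibroblast-like cells came in sufficient number from FVIO-MHT and PBS replicates 2 and 3. Hspa1b averaged 224 ± 109 CPM with FVIO-MHT and 8846 ± 1881 CPM with PBS (SD, n = 2 each), 38.6-fold lower, and Hspa1a was 26.3-fold lower. Both had an edgeR adjusted p of 0.0809. Both PBS libraries here are the pair that shares barcodes, so in this class that pair and the group cannot be told apart. Hsph1, Hsp90aa1 and Hspb1 were −3.59 ± 0.76, −2.27 ± 0.73 and −2.47 ± 0.68 (log2 ± SE). Cxcl2, a neutrophil-attracting chemokine, was 2.83 ± 0.77 (2.03 without FVIO-MHT replicate 2), and Tm4sf1, Tspo, Klf2 and Btg2 were 2.40 ± 0.75, 2.60 ± 0.81, 2.63 ± 0.92 and 2.18 ± 0.79. Without PBS replicate 2 Tspo was 3.65 and Klf2 4.00, and without PBS replicate 3 Btg2 was 3.52. Cygb and Akap9 were −2.78 ± 0.69 and −2.97 ± 0.75 (−2.18 without PBS replicate 2). Fth1, Ftl1 and Isg15 were 1.03 ± 0.73, −0.64 ± 0.59 and 1.77 ± 0.95. Fth1 was 0.14 without FVIO-MHT replicate 2 and 1.87 without PBS replicate 3. Isg15 was 0.42 without FVIO-MHT replicate 3 and 3.08 without PBS replicate 2. The edgeR adjusted p of the named genes other than Hspa1a and Hspa1b lay between 0.499 and 0.996. Hmox1 and Cd274 had too few UMIs to test. Camera called heat shock genes lower (median −2.27, 6 of 11 lower when adjusted over the list alone) and myeloid chemokines (0.82), nuclear oxidative phosphorylation (0.62) and ribosomal proteins (0.56) higher. Their adjusted p ran from 0.727 to 0.733 with an estimated correlation and from 1.82e-19 to 0.780 over their alternatives. Of 1048 genes, edgeR put 0 past the threshold (35 at an unadjusted p under 0.05) and DESeq2 put 2, Hspa1a and Hspa1b. Leaving out any library left a single one in its group, so counts of genes from those fits are not given. The chemokine call ended without FVIO-MHT replicate 2 (0.42) or PBS replicate 2 (0.69), the ribosomal call without FVIO-MHT replicate 3 (0.14) or PBS replicate 2 (0.50), and the oxidative phosphorylation call without FVIO-MHT replicate 3 (0.53) or PBS replicate 3 (0.87). Medians of calls that stayed moved by more than 1.5 times for heat shock without PBS replicate 3 (−0.99), chemokines without FVIO-MHT replicate 3 (1.36) or PBS replicate 3 (2.40), and oxidative phosphorylation without FVIO-MHT replicate 2 (0.98).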

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

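Alternatives chosen after the data had been seen are the stricter naming of clusters, the removal of barcodes found in more than 1 library, the removal of the cluster with markers of 2 classes, and the comparison without PBS replicates 2 and 3, which share barcodes. Of 94 counts of genes recomputed, 70 stayed within 1.5 times the reported count of 0 and 24 moved. Of 307 values of called lists, 189 kept their direction and call, 114 lost the call and 4 reversed, and of 801 values of named genes 67 passed the threshold. Of 140 differences in shares, 132 moved by less than the spread between replicates. Among these 132, the 9 with replicate number as a block and the 9 without the mitochondrial limit could not move, whatever the data. The 6 gene counts without the mitochondrial limit, among the 70 that stayed, could not move either. The cause was not tested for any change below unless stated.

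With at least 100 genes per cell the difference in share was −1.01 percentage points for macrophage/monocyte, −16.3 for tumour epithelial, 1.71 for pericyte/smooth muscle and −20.6 for unnamed cells. With at least 400 genes it was 16.9 for macrophage/monocyte and 4.58 for fibroblast cells, and FVIO-MHT replicate 1 kept 18 cells, 9 of them macrophage/monocyte. Both minimums also drew and named the clusters anew. The macrophage/monocyte difference was 10.2 points over named cells only and 0.573 with the stricter naming, which by construction leaves 1 macrophage cluster out. Without 1 library at a time, the differences ranged from 16.2 to 55.9 points for neutrophil (16.2 without FVIO-MHT replicate 1), from −43.2 to −25.0 for tumour epithelial and from 3.23 to 8.23 for macrophage/monocyte cells.

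DESeq2 put past the threshold 180 genes in whole tumours, 2 in macrophage/monocyte-like, 1 in neutrophil-like, 26 in tumour epithelial-like and 2 in fibroblast-like cells. Without the filter on low counts the counts were 2, 26, 1, 145 and 13 in that order. RLE size factors gave 2 genes in neutrophil-like cells. In fibroblast-like cells a minimum of 100 genes gave 3 and keeping doublets gave 1. Without PBS replicates 2 and 3, tumour epithelial-like cells had 7. Without 1 library at a time the counts ranged from 0 to 2 in macrophage/monocyte-like (2 without PBS replicate 1), from 0 to 248 in tumour epithelial-like (248 without FVIO-MHT replicate 2, 10 without PBS replicate 1), from 0 to 16 in T and NK-like (16 without PBS replicate 1, 1 without PBS replicate 3) and from 0 to 17 in fibroblast-like cells (12 without FVIO-MHT replicate 2, 17 without FVIO-MHT replicate 3).

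Replicate number as a block gave 1 gene in macrophage/monocyte-like, 29 in tumour epithelial-like, 2 in fibroblast-like cells and 0 in whole tumours, where it moved the median of all genes to −0.14 and ended the checkpoint call (0.79). These data do not show that the numbers pair libraries. Correlations were taken over each library's deviations from the mean log2 CPM of its group, not over whole profiles. That of same-numbered libraries was 0.163, 0.0198 and −0.0770, and that of FVIO-MHT replicate 3 with PBS replicate 2 was 0.310. FVIO-MHT replicate 1 did correlate best with PBS replicate 1, at −0.236 and 0.0277 with PBS replicates 2 and 3. With 3 libraries per group such correlations cannot exclude pairing.

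Camera with an estimated correlation and fry each called 0 lists in each of the 6 comparisons. Without 1 library at a time 1 to 2 lists were called in T and NK-like cells (1 without PBS replicate 1) and 2 to 5 in fibroblast-like cells (2 without FVIO-MHT replicate 3). Without 1 library at a time the whole tumour medians ranged from 0.19 to 1.44 for checkpoint genes and from −0.29 to 0.92 for hypoxia genes. Without FVIO-MHT replicate 1 they were 0.19, where the camera direction was lower, and −0.29. In tumour epithelial-like cells the ranges were −2.41 to 0.03 for MHC class I and −1.31 to 0.24 for hypoxia genes, with 0.0314 and 0.24 without FVIO-MHT replicate 3.

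There were too few libraries or cells for a fit in neutrophil-like cells with a block, without any 1 library or with at least 400 genes, in T and NK-like cells with a block, without FVIO-MHT replicate 2 or with either other gene minimum, and in fibroblast-like cells with at least 400 genes. These were not run.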

Other observations

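Chosen after the results they address had been seen were the tests of a batch, the comparison without PBS replicates 2 and 3, the correlations of shared barcodes and of the cluster, the permutation tests of list means, the bound of 50% on the gene minimums, the splits of the libraries and the bootstrap intervals. The gene minimums of 100 and 400, the permutation test of shares and the bounds on free RNA were set before.

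PBS replicates 2 and 3 shared 44 barcodes of 12 bases, and other pairs of libraries between 0 and 6. Of these, 33 had at least 200 genes in both libraries, with a median correlation of 0.552 between the counts of the same barcode and 0.262 between other barcodes. The UMI total in PBS replicate 3 divided by that in PBS replicate 2 was over 5 for 9 of them (median 11.0). It was under 2 for 24 (median 1.14), which can include barcodes with far more UMIs in PBS replicate 2. Among barcodes under the gene minimum, erythroid markers held 6983 CPM in FVIO-MHT replicate 3 and 3.99 CPM in PBS replicate 1, and dendritic markers 9.52 CPM in FVIO-MHT replicate 1 and 939 CPM in PBS replicate 1. The cluster with haemoglobin and keratin transcripts correlated across genes with the barcodes under the gene minimum of FVIO-MHT replicate 3 at 0.919 and with the tumour epithelial-like class of that library at 0.925, and that class correlated with those barcodes at 0.840. In FVIO-MHT replicate 2 and PBS replicates 1 and 2 the cluster correlated with the barcodes under the gene minimum at 0.570, 0.467 and 0.591, and the tumour epithelial-like class at 0.723, 0.697 and 0.875. Genes are not independent replicates.

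The first pattern is the lower level of heat shock genes with FVIO-MHT in 4 classes. Camera called it with the preset correlation alone, and every call was lost with an estimated correlation and with fry. In T and NK-like cells the FVIO-MHT side is replicate 2 alone. Neutrophil-like cells, with PBS replicate 1 alone as control and 6 of 18 members tested, Hspa1a and Hspa1b not among them, decide nothing here. A batch made of PBS replicates 2 and 3, grouped by their shared barcodes, stays open. In macrophage/monocyte-like cells PBS replicate 1 lay above the FVIO-MHT mean by 7.67% of the distance of the other PBS libraries (bootstrap interval −19.8 to 41.2%). In tumour epithelial-like cells the value was 43.9% (4.37 to 129%) and in T and NK-like cells 37.6% (1.95 to 59.1%). The intervals of the last 2 classes span the bound of 50%. By its rule the test lets 1 library count for a batch but not against one. It therefore cannot tell the batch and the treatment apart in any of these classes. The FVIO-MHT mean in macrophage/monocyte-like cells includes replicate 3, where cluster 15 gave 90.0% of the class. Without PBS replicates 2 and 3, the median of heat shock in macrophage/monocyte-like cells was 0.10 and the call ended. The same comparison gave −0.28 for heat shock in tumour epithelial-like cells and −0.53 for heat shock in whole tumours, and both camera calls stayed with the preset correlation, against PBS replicate 1 alone. The bootstrap resampled list members, which are not independent, and PBS replicate 1 is 1 library. Fibroblast-like cells had no other PBS library, so the batch and the group are wholly confounded in them. Free RNA stays open as well, since the median ratio of the list's members in a class to the barcodes under the gene minimum ran from 0.812 to 1.98 in these libraries. Barcodes under the gene minimum can also hold cells of low depth, so such ratios are not measured against free RNA alone. A change of composition stays open in tumour epithelial-like cells. Cluster 11, with Dnajb1 and Hspa1b among its leading genes, gave 44.7 and 36.8% of the class in PBS replicates 2 and 3. It gave 3.59% in PBS replicate 1 and 2.06 and 0.463% in FVIO-MHT replicates 2 and 3. Clusters were drawn from the same counts, so composition and expression are not told apart. The treatment stays open: in macrophage/monocyte-like cells the mean log2 CPM of the list was 6.39, 6.98 and 8.51 in FVIO-MHT libraries and 7.53, 10.3 and 9.66 in PBS libraries, with PBS replicate 1 below FVIO-MHT replicate 3 and an exact two-sided permutation p of 0.2.

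The second pattern is the neutrophil-like share. The bound of 50% was written for the lower gene minimum, and a minimum of 100 genes kept 106% of the difference of group means. The difference thus did not shrink at the lower minimum. A minimum of 400 genes kept 47.2%, so dependence on a higher minimum stays open. That value rests on FVIO-MHT replicate 1 with 8 of 18 cells neutrophil-like. An effect of the treatment may exist but stays open, because FVIO-MHT replicate 3 lay below every PBS library and the exact two-sided permutation p was 0.4. The interval of FVIO-MHT replicate 3 (0.0700 to 0.502%) overlaps that of PBS replicate 2 (0.284 to 1.17%), so their order is not settled. Differences in how tumours were sampled or dissociated were not tested.

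The third pattern is the higher level of cell cycle genes in tumour epithelial-like cells. A batch of PBS replicates 2 and 3 stays open. PBS replicate 1 lay below the FVIO-MHT mean by 140% of their distance (bootstrap interval over list members 83.5 to 285%). That library was therefore no nearer to FVIO-MHT than they were. By its rule the test lets 1 library count for a batch but not against one, so it cannot decide. The estimated correlation of the members was 0.532. Free RNA stays open: the median ratio of the members to the barcodes under the gene minimum was 1.55 (lower bound 1.46) and 2.19 in the FVIO-MHT libraries, against a bound of 1.5 set in advance. The treatment could be the cause, with a mean log2 CPM of 6.63 and 7.40 in FVIO-MHT libraries and 5.98, 6.12 and 6.45 in PBS libraries, and an exact two-sided permutation p of 0.2, the smallest that 2 against 3 libraries allow when the one-sided p is multiplied by 2. The summed level did not separate the groups, at 3556 CPM in FVIO-MHT replicate 2 and 3702 CPM in PBS replicate 3. Different clusters of tumour epithelial-like cells in each library, of which cluster 4 is led by cell cycle genes, leave a change of composition open.

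For the whole tumour and the macrophage/monocyte-like comparisons, 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 0 genes in both, and the highest of the other splits gave 0 and 1. With a real count of 0, all 10 of 10 splits give as many genes whatever the data, so the count says nothing about chance.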
